A study of Mus musculus with 12 samples.

How the data were processed

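RNA was measured by sequencing in aortic valves of mice at postnatal day 10. The 12 libraries fall into 3 groups of 4: wildtype, and libraries labelled Notch1+/-;Gata5+/- and Notch1+/-;Gata5-/-. Each library is a pool of 3 valves, so the unit of replication is the pool. Per the labels, messenger RNA was selected by poly-A, reads were trimmed with Trim Galore and aligned with STAR 2.7.10b to GRCm39, and DESeq2 1.34.0 was used. The counting tool, the annotation release, the strand setting and the handling of duplicates are not given in the sources used here. The protocol text describes directional and non-directional libraries, so the strand of these libraries is unknown, and counts of genes that overlap on opposite strands may be shared.

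The deposited count table holds raw counts of 20620 genes, a whole number per gene and library. Its smallest total over the 12 libraries was 33 and no gene was at 0 in more than 9 libraries, so genes below some minimum were absent from it. The authors also deposited a table of 13959 genes, with a mean normalized signal, a log2 fold change, its standard error and a Wald statistic (both scores), a p-value and an adjusted p-value. The table names no comparison. Its log2 fold changes matched those of a DESeq2 refit of the deposited counts for Notch1+/-;Gata5-/- against wildtype, with a largest absolute difference of 1.655e-04. Gene symbols came from that table for 13959 identifiers and from a GENCODE mouse annotation of an older build for 6077 more, and 584 identifiers had no symbol. That annotation was used for names and for gene neighbourhoods, and no coordinates are given here.

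The totals were 13866604 to 25059653 counts per library. A gene at 0 in a library of this depth could still hold up to 3 counts, which sets a floor of 0.120 to 0.216 CPM (counts scaled to a common library total) per library. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

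Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 19346 genes and removed 1274. Libraries were scaled by TMM, and CPM values below are TMM-normalized, with the SD over the 4 libraries of a group. A robust quasi-likelihood model with a term per group was fitted to all 12 libraries, and each pair of groups was compared by a quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.680. Values of single genes and list scores were also compared by a two-sided exact permutation test over the 35 distinct splits of 8 libraries into 4 and 4. The smallest p this test can give is 0.0286.

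For gene groups, 38 lists with 734 distinct genes were fixed before the data were examined, as were the groups, the tests, the thresholds, the rule for named genes and most of the other settings tried. Some genes belong to several lists, such as Comp (chondrogenic and matricellular) and Fabp3 (ventricular and fatty acid oxidation), so the lists are not independent. The lists cover signalling, matrix, valve cell types, other cell types that a dissection could include, cell states and sample checks. Each list was tested with camera in limma 3.58.1 on voom values, two-sided, with a preset inter-gene correlation of 0.01, and called at an adjusted p under 0.05 over the 38 lists. The test was repeated with a correlation estimated from the data and with fry, whose directional p tests whether a list's genes move, on balance, to one side. A list score is the mean log2 CPM of the list's members in a library.

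The genes named were Notch1 and Gata5. To these were added the called genes with a symbol that is not a provisional model, a mean log2 CPM of at least 1 and groups without overlap (up to 6 per direction by fold change and 4 by p, or 4 and 2 for the comparison of both mutant groups). From each called list came the 4 members with the smallest p, and from the lists of Notch, GATA, collagen, proteoglycan and elastic fibre genes the 3 with the smallest p. Any other gene named is marked as chosen after its values were seen.

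Other settings chosen beforehand were other normalizations (RLE, upper quartile), no filter and a stricter filter (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0, limma-voom with and without quality weights, the authors' thresholds (adjusted p under 0.1 and absolute log2 fold change over 0.58), only the 8 libraries compared, each library left out in turn, the replicate number as a block, and a heart muscle score or a Y-linked score as a covariate. Chosen after seeing the data were a fit without the 2 libraries least correlated with the others, the number of genes at 0 as a covariate, and 2 settings for the libraries numbered 4. The closing section gives their effect.

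The calling was tested on simulated data with the spread per gene that the model estimated from these libraries. Of 100 genes shifted by 0.75 on the log2 scale, 11 to 16 were called across the 3 comparisons, and of 100 shifted by 1.5, 55 to 63 were called. Among those with a mean of at least 50 CPM, 9 of 22, 8 of 17 and 9 of 19 were called at 0.75. At 1.5 these were 21 of 23, 24 of 26 and 33 of 35. The simulations of shared genes below used the same spread, which did not match that of these libraries, so these shares may not hold for them. No library was left out of the comparisons. The position of called genes near Notch1 and Gata5, both on chromosome 2, was tested with Fisher's exact test in a window of 20 Mb.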

Results

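Messenger RNA was counted in 12 pools of 3 mouse aortic valves each, collected at postnatal day 10, with 4 pools per group. The groups were wildtype and libraries labelled Notch1+/-;Gata5+/- and Notch1+/-;Gata5-/-, called here the double-heterozygous-labelled and the Gata5-null-labelled libraries. Notch1 encodes a receptor of cell-to-cell signalling and Gata5 a zinc finger transcription factor of the developing heart. The total counts were 19206388, 20899533, 19755688 and 21450396 in wildtype replicates 1 to 4, in that order. They were 18102969, 20025835, 20172172 and 21573022 in the double-heterozygous-labelled libraries and 20310218, 15139894, 13866604 and 25059653 in the Gata5-null-labelled ones. Of the deposited genes, Gata5-null-labelled replicate 3 had 6000 at 0 and wildtype replicate 2 had 3208, against 1017 to 2908 in the other 10 libraries. The same libraries had the lowest mean Spearman correlations with the others across genes, 0.892 and 0.925, against 0.933 to 0.950.

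Gata5 (ENSMUSG00000015627) had no count in any of the 4 Gata5-null-labelled libraries, over 74376369 counts in all. It had 56, 18, 46 and 19 counts in wildtype replicates 1 to 4, a mean of 1.77 CPM ± 1.03 (SD, n = 4). In the double-heterozygous-labelled libraries it had 97, 112, 98 and 15 counts, a mean of 4.09 CPM ± 2.27 (SD, n = 4). With a floor of 3 counts over the group, 0.0403 CPM, Gata5 was at least 43.9-fold lower in the Gata5-null-labelled libraries than in wildtype. It was at least 101.5-fold lower there than in the double-heterozygous-labelled libraries (exact permutation p = 0.0286 for each, two-sided, the smallest this design can give). The edgeR test did not call Gata5 (adjusted p = 0.204 and 0.560), and DESeq2 did (adjusted p = 1.700e-04 and 2.781e-06). The higher mean in the double-heterozygous-labelled libraries than in wildtype did not exceed the spread between replicates (log2 fold change 1.21, SE 1.13, exact permutation p = 0.229). At this depth the counts did not show a loss of 1 Gata5 copy.

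Notch1 (ENSMUSG00000026923) was not lower in the libraries labelled Notch1+/-. Its mean was 128 CPM ± 26.4 in wildtype, 172 CPM ± 20.6 in the double-heterozygous-labelled and 185 CPM ± 29.5 in the Gata5-null-labelled libraries (SD, n = 4 each). The log2 fold changes against wildtype were 0.42 (SE 0.15, adjusted p = 1) and 0.53 (SE 0.15, adjusted p = 0.582), with an exact permutation p of 0.0571 for each. The labels do not say which part of Notch1 the allele lacks, so these counts do not check the Notch1 genotype.

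**Figure D1:**
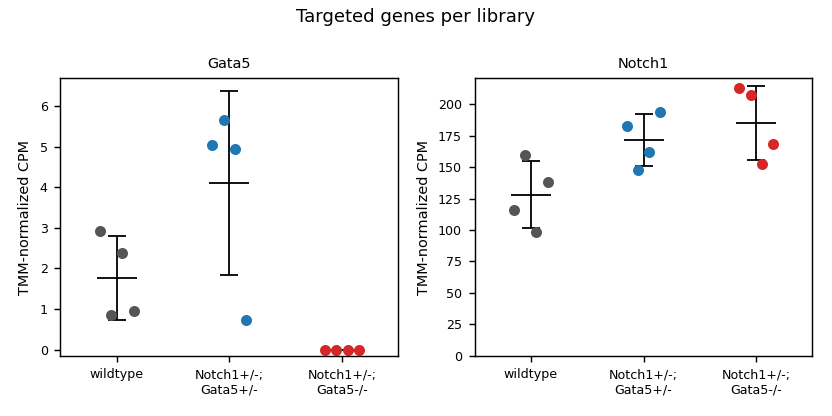
Each point is a library; the vertical axes give TMM-normalized CPM of Gata5 and Notch1, the bar is the group mean and the whiskers the SD of 4 libraries. Gata5 is at 0 in the 4 Gata5-null-labelled libraries, and Notch1 has means of 128, 172 and 185 CPM from left to right.

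The comparison of the Gata5-null-labelled libraries with wildtype asks what differs in the valve between a genotype labelled as lacking 1 Notch1 copy and both Gata5 copies and wildtype, so the labels of both genes differ. Genes of the contractile apparatus of smooth muscle were lower. Myh11 (ENSMUSG00000018830), the smooth muscle myosin heavy chain, fell from 2357 CPM ± 365 to 1397 CPM ± 208 (SD, n = 4 each), a log2 fold change of -0.75 (SE 0.12, adjusted p = 0.0136). Mylk (ENSMUSG00000022836), myosin light chain kinase, fell from 442 CPM ± 47.2 to 263 CPM ± 28.3 (log2 fold change -0.75, SE 0.12, adjusted p = 0.00861). Cnn1 (ENSMUSG00000001349), the actin-binding calponin 1, fell from 276 CPM ± 50.3 to 157 CPM ± 28.6 (log2 fold change -0.81, SE 0.15, adjusted p = 0.0365). Synpo2 (ENSMUSG00000050315), an actin-bundling protein of muscle, fell from 380 CPM ± 30.4 to 214 CPM ± 36.2 (log2 fold change -0.83, SE 0.13, adjusted p = 0.00824). The other called gene was Itih4 (ENSMUSG00000021922), of the inter-alpha-trypsin inhibitor heavy chain family, from 77.4 CPM ± 12.1 to 34.4 CPM ± 6.18 (log2 fold change -1.17, SE 0.17, adjusted p = 0.00824). For each of the 5 genes the groups did not overlap (exact permutation p = 0.0286). The genes were chosen by their p in these libraries and named only without overlap, so this p is no separate support. The elastin gene Eln took 10.6% ± 2.15 of all counts in wildtype and 7.79% ± 1.13 in the Gata5-null-labelled libraries (SD, n = 4 each), and its own log2 fold change was -0.50 (SE 0.15, adjusted p = 0.738).

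**Figure D2:**
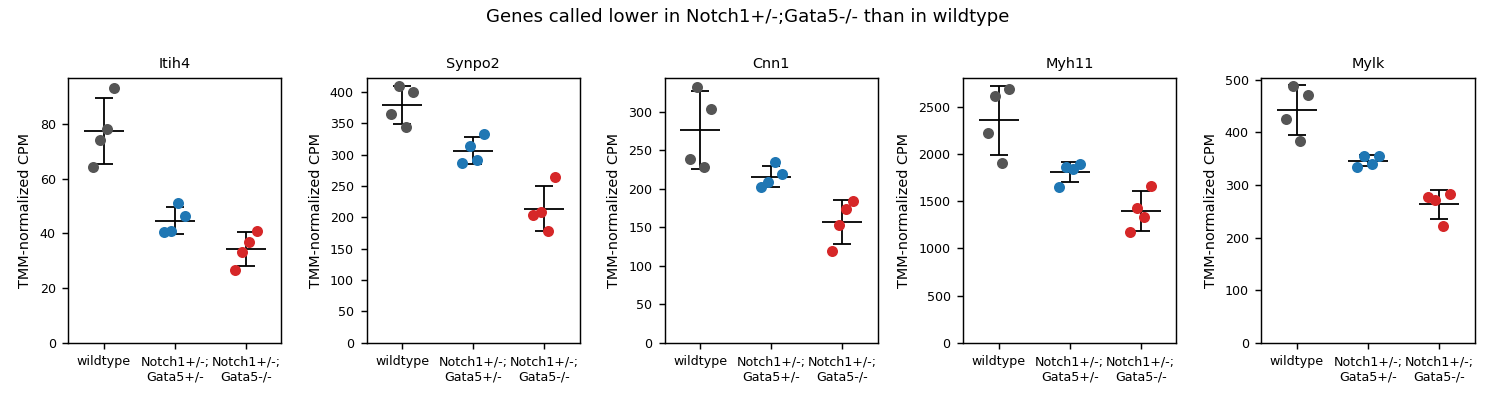
Each point is a library; the vertical axes give TMM-normalized CPM of the 5 called genes, starting at 0, with the group mean as a bar and the SD of 4 libraries as whiskers. In each panel the Gata5-null-labelled libraries lie below the wildtype libraries, and Itih4 has group means of 77.4, 44.7 and 34.4 CPM from left to right.

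The edgeR test called 5 of 19346 genes, 0 higher and 5 lower, and 1044 genes had an unadjusted p under 0.05 (394 higher, 650 lower). Chance alone gives a share of 0.05 of the genes tested, which is close to this count of 1044. DESeq2 called 45 genes, 8 higher and 37 lower. Many of these were near the floor, at 0 in all 4 Gata5-null-labelled libraries and low in wildtype. Examples, named after their values were seen, are Gm37973 (wildtype mean 0.933 CPM) and Slc9a2 (1.67 CPM), with edgeR adjusted p of 0.770 and 0.582. Others, among them the 5 edgeR calls, had counts in every library of both groups. No gene was called with only the 8 libraries of both groups in the fit (504 at an unadjusted p under 0.05) or with a Y-linked score as a covariate (582). With the 8 libraries the fold changes of Itih4, Synpo2, Mylk, Myh11 and Cnn1 were -1.17, -0.83, -0.75, -0.75 and -0.81, as in the fit of all 12 (adjusted p = 0.0695, 0.0845, 0.113, 0.200 and 0.278). The count was 2 without wildtype replicate 2 (which kept neither Myh11, Mylk nor Cnn1), 3 without Gata5-null-labelled replicate 1 (neither Myh11 nor Cnn1), and 21 without Gata5-null-labelled replicate 4. Cnn1 and Myh11 were also not called without Gata5-null-labelled replicate 2 (adjusted p = 0.178 and 0.0621), nor Cnn1 without wildtype replicate 4 (adjusted p = 0.141). Without both libraries that stand apart, wildtype replicate 2 and Gata5-null-labelled replicate 3, none of the 4 contractile genes was called (log2 fold change -0.71 and adjusted p = 0.0788 for Synpo2, -0.62 and 0.124 for Mylk, -0.67 and 0.159 for Myh11, -0.75 and 0.107 for Cnn1), and Itih4 was (-1.22). The call of Cnn1 was lost with the stricter filter (adjusted p = 0.0568), in limma-voom with quality weights (adjusted p = 0.0517) and with replicates 1 to 3 only (adjusted p = 0.0978). In every fit that ended a call of the 4 contractile genes the fold change lay between -0.85 and -0.62.

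The list of smooth muscle and myofibroblast genes fell as a group. Of its 21 members, 19 had a negative log2 fold change, and the mean was -0.43. Lower members adjusted over the list alone numbered 10, and over all genes tested 4. The camera test gave an adjusted p of 6.12e-15, which became an adjusted p of 0.141 (unadjusted 0.00370) with an estimated correlation, and fry gave an adjusted p of 0.0316. Members that did not pass on their own over all genes in edgeR included Tagln (-0.65, adjusted p = 0.0978), Acta2 (-0.57, adjusted p = 0.375) and Actg2 (-1.61, adjusted p = 0.341), which were named after their values were seen. DESeq2 called each of them (adjusted p = 0.00190, 0.0266 and 0.0234). The list score was 7.56 ± 0.13 in wildtype, 7.39 ± 0.09 in the double-heterozygous-labelled and 7.07 ± 0.22 in the Gata5-null-labelled libraries (SD, n = 4 each). The exact permutation p of the score for Gata5-null-labelled against wildtype was 0.0286, or 0.362 when adjusted over the 38 lists.

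**Figure D3:**
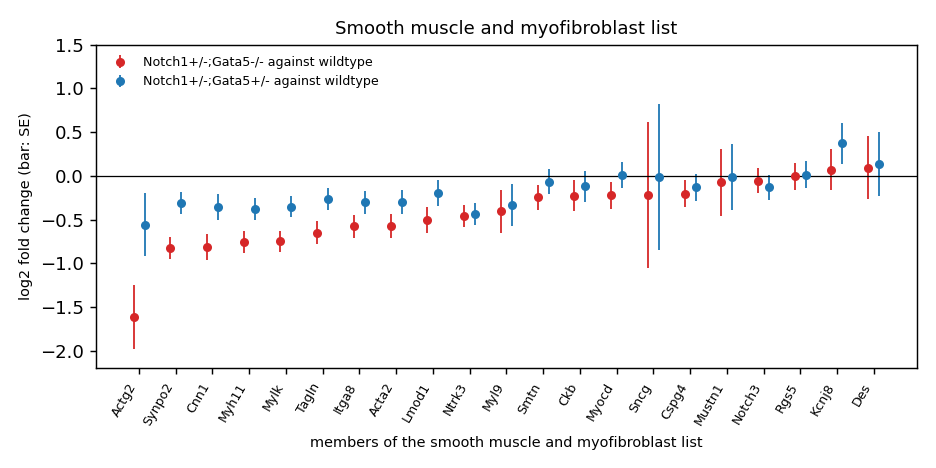
The vertical axis gives the log2 fold change against wildtype of each of the 21 members of the smooth muscle and myofibroblast list, with its SE as a bar, for the Gata5-null-labelled (red) and the double-heterozygous-labelled (blue) libraries. Of the red points 19 are below 0, and of the blue points 17.

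For members of lists below, square brackets after a log2 fold change give its range over the fits that leave out 1 library, where 1 of these moved it by over 1.5 times. Among matrix and valve cell lists in the same comparison, camera called the chondrogenic and the endothelial lists higher. The chondrogenic list had 17 of 20 members positive with a mean log2 fold change of 0.36 (adjusted p = 6.12e-05, and adjusted p = 0.471 with an estimated correlation). Its members included the cartilage collagens Col2a1 (1.37, SE 0.51) and Col11a1 (0.69, SE 0.26) and the cartilage matrix proteins Matn4 (1.05, SE 0.42) and Comp (0.97, SE 0.39), and none of its members passed over all genes or adjusted over the list alone. Without Gata5-null-labelled replicate 1 the list's mean was 0.12 and its adjusted p 0.0865. The endothelial list had 19 of 24 members positive, with a mean of 0.18 (adjusted p = 0.00623, and adjusted p = 0.471 with an estimated correlation). Its member with the smallest p was Nfatc1, a transcription factor of valve endocardium (log2 fold change 0.80, SE 0.22, adjusted p = 0.525), followed by Erg (0.37), Flt1 (0.35 [0.18 to 0.52]) and Prox1 (0.30). The call of the endothelial list was lost without wildtype replicate 3 (adjusted p = 0.0805) and without Gata5-null-labelled replicate 4 (mean 0.10, adjusted p = 0.0721).

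The remaining lists of signalling and matrix genes fixed for this tissue were not called. Of 23 Notch pathway genes and targets, 14 were positive (adjusted p = 0.117), among them the fringe genes Lfng (0.998, SE 0.44) and Mfng (1.27, SE 0.63), which modify Notch receptors. Of 14 GATA factors and cofactors, 9 were positive with a median log2 fold change of 0.04, which is the same with Gata5 at its bound (adjusted p = 0.570), with Tbx20 at 0.25 and Gata4 at 0.19. Of 21 collagen genes, 12 were positive (adjusted p = 0.0646), with Col8a1 at 0.57 and Col16a1 at 0.51 but Col14a1 at -0.42. Adjusted over the list alone, 2 collagen genes were higher and 1 lower. The proteoglycan list (adjusted p = 0.259) had Acan at 0.44, Hapln1 at 0.53 [0.20 to 0.67] and Vcan at 0.22 [0.14 to 0.29]. The elastic fibre list was even, with 9 positive and 9 negative members (adjusted p = 0.464). Adjusted over that list alone, 2 members were higher and 3 lower, and its smallest p-values were those of Eln, Loxl1 (-0.41) and Mfap4 (-0.40).

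Heart muscle and mitochondrial lists also differed. Camera called the ventricular and general cardiomyocyte list higher, with 21 of 25 members positive and a mean log2 fold change of 0.18 (adjusted p = 5.75e-06, and adjusted p = 0.533 with an estimated correlation). Its members included Myh7 (0.91 [0.27 to 1.42], lowest without Gata5-null-labelled replicate 1), Fabp3 (0.45 [0.20 to 0.65]), Tnnc1 (0.39 [0.15 to 0.59]) and Myl2 (0.38 [0.13 to 0.61]), the last 3 at 0.20, 0.15 and 0.13 without wildtype replicate 2. The atrial cardiomyocyte list was called lower, with 10 of 12 members negative and a mean of -0.87 (adjusted p = 0.0137, and adjusted p = 0.471 with an estimated correlation), with Sln at -1.84 [-2.32 to -0.84], Stard10 at -1.05 and Nppa at -0.75 but Kcna5 at 0.69. Sln was at -0.84 without wildtype replicate 3. Higher lists were the mitochondrially encoded genes (7 of 7 positive, mean 0.39, adjusted p = 6.04e-06, with ND4 at 0.49 [0.29 to 0.66], ND1 at 0.47, COX1 at 0.45 [0.27 to 0.61] and CYTB at 0.40 [0.20 to 0.58]) and fatty acid oxidation (21 of 23 positive, mean 0.17, adjusted p = 5.29e-05, with Ech1 at 0.35, Cd36 at 0.33 [0.15 to 0.45] and Acaa2 at 0.25 [0.09 to 0.41]). Oxidative phosphorylation was higher too (23 of 28 positive, mean 0.10, adjusted p = 7.96e-04, with Ndufa2 at 0.39 [0.07 to 0.59], Ndufa4 at 0.35 [0.16 to 0.63], Cycs at 0.24 [0.04 to 0.48] and Uqcrc2 at 0.20 [0.07 to 0.35]). The lower ends of these ranges came without wildtype replicate 2, except for CYTB (without Gata5-null-labelled replicate 4) and Ndufa2 (without Gata5-null-labelled replicate 3). These 3 lists had an adjusted p of 0.471, 0.533 and 0.617 with an estimated correlation. The erythroid list was higher, with 5 of 8 positive and a mean of 0.38 (adjusted p = 0.0402, and adjusted p = 0.471 with an estimated correlation), with Slc4a1 at 1.63 [0.99 to 2.05], Hbb-bt at 0.38 [0.09 to 0.69] and Hbb-b1 at 0.30 [0.11 to 0.62].

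The mitochondrial genome took 2.45% ± 0.805 of counts in wildtype, 2.65% ± 0.384 in the double-heterozygous-labelled and 3.15% ± 0.477 in the Gata5-null-labelled libraries (SD, n = 4 each). Wildtype replicate 2, with the lowest share at 1.46%, also had the lowest share of counts in the heart muscle gene Ttn, 1.344%, a gene chosen after its values were seen. Without wildtype replicate 2 the mean of the ventricular list was -0.04 (adjusted p = 0.896), that of oxidative phosphorylation -0.07, that of fatty acid oxidation 0.04 (adjusted p = 0.101) and that of the mitochondrially encoded genes 0.21. Without Gata5-null-labelled replicate 4 the calls of oxidative phosphorylation (mean -0.01, adjusted p = 0.223), fatty acid oxidation (mean 0.06, adjusted p = 0.0580) and the atrial list (adjusted p = 0.0509) were lost. Without that library the mitochondrially encoded mean was 0.18 and the ventricular mean 0.08, both still called. Without wildtype replicate 3 or 4 the means were 0.34 and 0.29 for the ventricular list, 0.26 and 0.15 for oxidative phosphorylation and 0.26 and 0.28 for fatty acid oxidation. Without Gata5-null-labelled replicate 1 the last 2 lists had means of 0.20 and 0.27. The atrial call was lost without wildtype replicate 3 (mean -0.46, adjusted p = 0.114) and with the covariate of genes at 0 (adjusted p = 0.0658). With the heart muscle covariate the calls of fatty acid oxidation (mean 0.03, adjusted p = 0.0775), oxidative phosphorylation (mean -0.06, adjusted p = 0.411) and the ventricular list, from which that score is made (mean 0.01, adjusted p = 0.502), were lost, while the mitochondrially encoded genes stayed called with a mean of 0.20. Without both libraries that stand apart these 3 calls were lost too (means 0.02, -0.06 and -0.02, adjusted p = 0.463, 0.463 and 0.911).

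The erythroid call was lost without wildtype replicate 1 (mean 0.59, adjusted p = 0.126), wildtype replicate 2 (mean 0.61, adjusted p = 0.0655) or Gata5-null-labelled replicate 2 (mean 0.30, adjusted p = 0.198). Its mean was 0.73 without wildtype replicate 3, 1.32 without wildtype replicate 4 and 0.69 without Gata5-null-labelled replicate 4. The call was also lost with the replicate number as a block (adjusted p = 0.0508), with the heart muscle covariate (adjusted p = 0.107), without both libraries that stand apart (adjusted p = 0.0742) and with an indicator of the libraries numbered 4 (adjusted p = 0.0551). The erythroid mean was 1.29 with replicates 1 to 3 only and 0.63 with the covariate of genes at 0. In all, camera called 9 of 38 lists, 7 higher and 2 lower. With an estimated correlation it called 0 (2 lists at an unadjusted p under 0.05), and fry called 1, the smooth muscle list.

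**Figure D4:**
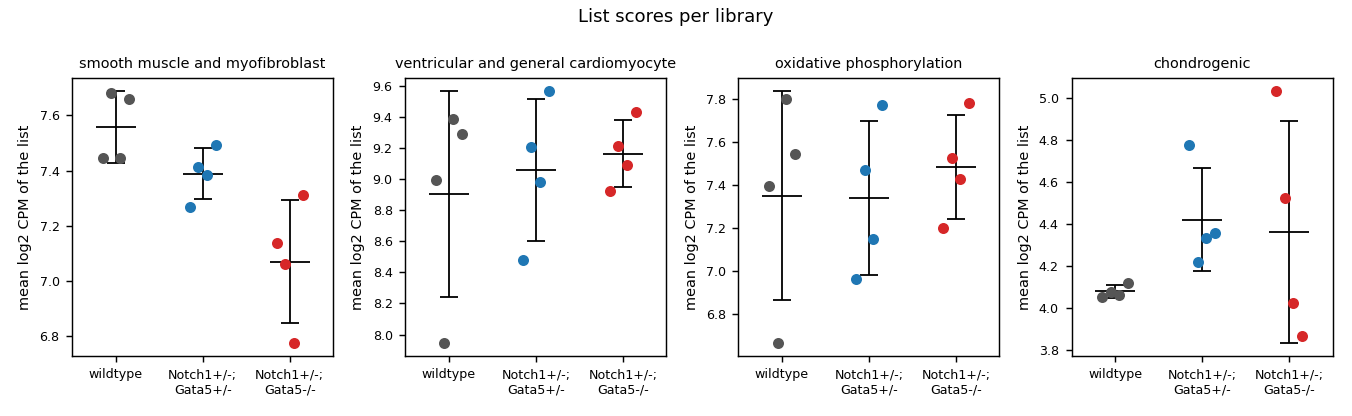
Each point is a library; the vertical axes give the mean log2 CPM of the members of 4 lists, with the group mean as a bar and the SD of 4 libraries as whiskers. The smooth muscle score has means of 7.56, 7.39 and 7.07 from left to right, while the Gata5-null-labelled and wildtype libraries overlap in the other 3 panels.

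The authors' deposited table, which matches Gata5-null-labelled against wildtype, marks 33 of its 13959 genes as changed, 22 lower and 11 higher. The lowest mean normalized signal in the authors' deposited table, made with DESeq2, is 20.03. All 5 genes called by edgeR here are among the 33 marked in the authors' deposited table, and 6 of the 33 belong to the smooth muscle list. All 33 had the same sign in edgeR, and 8 passed the authors' thresholds there, an adjusted p under 0.1 and an absolute log2 fold change over 0.58. Named after their values were seen, the 3 that passed besides the calls were Lrrc17 (-0.95, adjusted p = 0.0551), Cbr2 (-1.19, adjusted p = 0.0551) and Tagln. Marked genes that did not pass in edgeR, also named after their values were seen, included the basement membrane collagen gene Col4a6 (-0.74, adjusted p = 0.139) and Robo2 (0.77), a receptor for guidance cues.

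The comparison of the double-heterozygous-labelled libraries with wildtype asks what differs between libraries labelled as lacking 1 copy of each gene and wildtype, and the counts above did not show a loss of either. No gene was called by edgeR, and 242 had an unadjusted p under 0.05 (156 higher, 86 lower). That is below the share of 0.05 that chance alone gives over the 19346 genes tested. Of the 35 splits of these 8 libraries into 4 and 4, 22 gave at least 242 such genes, and the highest of the others was 912. Every split thus lay below that share, so it is no firm reference here. By the splits the count is no sign of a difference, and the absence of calls does not show that the groups are alike. The count was 440 with only the 8 libraries in the fit and 852 in limma-voom with quality weights. DESeq2 called 1 gene, the provisional model Gm29253, named after its values were seen, which was at 0 in the 4 wildtype libraries. In the double-heterozygous-labelled libraries it averaged 1.24 CPM, all of it from 1 library at 4.95 CPM. The smooth muscle list was again lower by camera, with 17 of 21 members negative and a mean log2 fold change of -0.18 (adjusted p = 1.66e-09, and adjusted p = 0.197 with an estimated correlation). Adjusted over the list alone 3 members were lower, and over all genes tested 0. Its members with the smallest p were Ntrk3 (-0.43, SE 0.12), Myh11 (-0.38, SE 0.12), Mylk (-0.35, SE 0.12) and Synpo2 (-0.31, SE 0.13), with no overlap between the groups (exact permutation p = 0.0286 each, adjusted p = 1 over all genes). They were chosen by their p in these libraries, so the permutation p is no separate support. Itih4 averaged 44.7 CPM ± 5.10 (SD, n = 4), a log2 fold change of -0.79 (SE 0.17, adjusted p = 1).

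Of the matrix and interstitial cell lists in the same comparison, camera called 4 higher with the preset correlation and 0 with an estimated one. The chondrogenic list had 16 of 20 members positive and a mean of 0.32 (adjusted p = 0.00299, and adjusted p = 0.700 with an estimated correlation), with Col9a3 at 0.86, Comp at 0.71, Sox9 at 0.48 [0.31 to 0.63] and Col11a1 at 0.43 [0.23 to 0.54]. The list of matricellular proteins, secreted regulators of cell and matrix contact, had 18 of 22 positive and a mean of 0.17 (adjusted p = 0.00973, and adjusted p = 0.197 with an estimated correlation), with Ccn1 at 0.53, Cilp at 0.30 [0.13 to 0.40] and Cthrc1 at 0.29. The collagen list had 15 of 21 positive and a mean of 0.17 (adjusted p = 0.0110, and adjusted p = 0.840 with an estimated correlation), with Col8a1 at 0.54, Col16a1 at 0.34 and Col12a1 at 0.31 [0.19 to 0.39] but Col14a1 at -0.32. The list of valve interstitial cells and fibroblasts had 17 of 20 positive and a mean of 0.14 (adjusted p = 0.0144, and adjusted p = 0.197 with an estimated correlation), with Penk at 0.64 [0.38 to 0.99], Pi16 at 0.27 [0.17 to 0.34], Dcn at 0.16 [0.08 to 0.27] and Lum at 0.14 [0.08 to 0.19]. The proteoglycan and elastic fibre lists were not called. All 4 calls were lost without wildtype replicate 1 (adjusted p = 0.0566, 0.0566, 0.166 and 0.0566). The collagen, matricellular and interstitial calls were also lost without wildtype replicate 3 (adjusted p = 0.549, 0.153 and 0.0790), the collagen call without double-heterozygous-labelled replicate 3 (adjusted p = 0.553), and the chondrogenic (mean 0.18) and interstitial calls without double-heterozygous-labelled replicate 1 (adjusted p = 0.112 each).

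Of heart muscle lists in this comparison, the ventricular list was called higher, with 21 of 25 members positive and a mean of 0.10 (adjusted p = 0.0252), including Myoz2 at 0.27 [0.0061 to 0.61], Actn2 at 0.24 [0.03 to 0.44], Ckmt2 at 0.21 [-0.02 to 0.44] and Ldb3 at 0.17 [-0.04 to 0.32]. The atrial list was called lower, with 8 of 12 negative and a mean of -0.21 (adjusted p = 0.0144), with Stard10 at -0.81, Kcnj3 at -0.72 [-1.20 to -0.29] and Nppa at -0.61 [-0.83 to -0.37] but Bmp10 at 2.18 [1.29 to 3.90]. The ranges of Kcnj3 and Bmp10 end at the fits without wildtype replicate 3 and double-heterozygous-labelled replicate 4. With an estimated correlation the adjusted p of the ventricular and atrial lists was 0.843 and 0.700. Without wildtype replicate 2 the ventricular mean was -0.13 and the list was called lower, without double-heterozygous-labelled replicate 4 its mean was -0.09, and without double-heterozygous-labelled replicate 2 its adjusted p was 0.236. Its mean was 0.26, 0.21 and 0.26 without wildtype replicate 3, wildtype replicate 4 and double-heterozygous-labelled replicate 1. The atrial call was lost without wildtype replicate 1 (adjusted p = 0.0566), wildtype replicate 3 (mean 0.19, adjusted p = 0.254) and double-heterozygous-labelled replicate 1 (mean -0.02, adjusted p = 0.487). The atrial mean was -0.38 without wildtype replicate 2 and -0.71 without double-heterozygous-labelled replicate 4. With the covariate of genes at 0 the ventricular and atrial calls were lost (means 0.07 and -0.32, adjusted p = 0.205 and 0.0988). The ventricular call was lost with replicates 1 to 3 only (mean 0.02, adjusted p = 0.226) and with the heart muscle covariate (adjusted p = 0.813), and without both libraries that stand apart the list was called lower (mean -0.13). The atrial mean was -0.80 with replicates 1 to 3 only, -0.44 with the heart muscle covariate and -0.43 with the stricter filter. Lists not called included the Notch genes (12 of 23 positive, adjusted p = 0.672, with Lfng at 0.90 and Jag1 at -0.25) and the GATA genes (7 of 14 positive, adjusted p = 0.672, with Hand2 at 0.43, Tbx20 at 0.16 [0.10 to 0.21] and Tbx5 at -0.85 [-1.40 to -0.25]). The proteoglycan list (13 of 21 positive, adjusted p = 0.0593) had Prg4 at 0.38 [0.20 to 0.54], Hapln1 at 0.37 [0.23 to 0.50] and Vcan at 0.19, and the elastic fibre list (7 of 18 positive, adjusted p = 0.265) had Eln at -0.32 [-0.42 to -0.20], Efemp2 at -0.29 and Fbn2 at 0.19. Camera called 7 lists, 5 higher and 2 lower, of which 0 were called with an estimated correlation (3 at an unadjusted p under 0.05) and 0 by fry. The count was 2 without wildtype replicate 1 and 12 without wildtype replicate 4.

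The comparison of the Gata5-null-labelled with the double-heterozygous-labelled libraries is the direct test of the remaining Gata5 copy, since the Notch1 label is the same in both groups. No gene was called by edgeR (smallest adjusted p 0.560, that of Gata5), and 616 had an unadjusted p under 0.05 (213 higher, 403 lower). That count too was below the share that chance alone gives, and 16 of the 35 splits of these 8 libraries gave at least as many. DESeq2 called 3 genes, Gata5, Upb1 and the unnamed ENSMUSG00000120665, the last 2 named after their values were seen. Upb1 averaged 0.0207 CPM against 2.27 CPM. ENSMUSG00000120665 was at 0 in the Gata5-null-labelled libraries and averaged 2.01 CPM in the double-heterozygous-labelled ones, all of it from 1 library at 8.04 CPM. Without Gata5-null-labelled replicate 2, 3 or 4 edgeR called 1 gene each. The smooth muscle list was lower by camera, with 20 of 21 members negative and a mean log2 fold change of -0.25 (adjusted p = 2.32e-05, and adjusted p = 0.940 with an estimated correlation). Adjusted over the list alone 6 members were lower, and over all genes tested 0. Synpo2 was at -0.52, Cnn1 at -0.46 and Mylk at -0.40, without overlap between the groups (exact permutation p = 0.0286 each), and Myh11 was at -0.37 (exact permutation p = 0.0571). These members too were chosen by their p in these libraries, so the permutation p is no separate support.

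Lists of energy metabolism and heart muscle were called higher in this comparison with the preset correlation, and none was with an estimated one (adjusted p of at least 0.940 for every list). Oxidative phosphorylation had 23 of 28 members positive and a mean of 0.13 (adjusted p = 2.32e-05), with Ndufa2 at 0.59 [0.27 to 0.79], Ndufb9 at 0.31, Ndufs4 at 0.31 [0.19 to 0.54] and Uqcrc2 at 0.29 [0.22 to 0.43]. The mitochondrially encoded genes had 7 of 7 positive and a mean of 0.22 (adjusted p = 0.00299), with ND1 at 0.33 [0.18 to 0.46], ND4 at 0.33 [0.13 to 0.46], ND2 at 0.28 [0.05 to 0.45] and COX1 at 0.24 [0.07 to 0.42]. Fatty acid oxidation had 16 of 23 positive and a mean of 0.08 (adjusted p = 0.00299), with Ech1 at 0.37, Etfb at 0.31 [0.16 to 0.52], Cpt1b at 0.24 [0.08 to 0.41] and Etfa at 0.22 [0.14 to 0.34]. The ventricular list had 14 of 25 positive and a mean of 0.08 (adjusted p = 0.00683), with Myh7 at 0.76 [0.12 to 1.02], Myl2 at 0.39 and Fabp3 at 0.36 [0.24 to 0.59] but Ckmt2 at -0.25 [-0.42 to -0.13]. These 4 calls were lost without Gata5-null-labelled replicate 4, where the means were 0.02, 0.0066, -0.03 and -0.02 (adjusted p = 0.204, 0.535, 0.535 and 0.449). They were also lost without double-heterozygous-labelled replicate 1, where the means were 0.04, 0.10, -0.02 and -0.07 (adjusted p = 0.227, 0.232, 0.736 and 0.892). Without double-heterozygous-labelled replicate 4 the means were 0.30, 0.37, 0.23 and 0.27, and without Gata5-null-labelled replicate 1 they were 0.24, 0.34, 0.18 and 0.16. Without double-heterozygous-labelled replicate 3 those of oxidative phosphorylation, fatty acid oxidation and the ventricular list were 0.07, 0.05 and 0.04. With the heart muscle covariate the ventricular call was lost (mean 0.01, adjusted p = 0.465), and the other 3 lists stayed called with means of 0.07, 0.13 and 0.03. With the covariate of genes at 0 the 4 means were 0.24, 0.46, 0.12 and 0.21, and with the Y-linked covariate 0.23, 0.36, 0.19 and 0.17.

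The endothelial list was called higher with the preset correlation, with 17 of 24 members positive and a mean of 0.11 (adjusted p = 0.0353, and adjusted p = 0.940 with an estimated correlation), including Nfatc1 at 0.48, Klf2 at 0.45 [0.03 to 0.67], Egfl7 at 0.24 [0.13 to 0.33] and Erg at 0.20 [0.11 to 0.32]. Klf2 was at 0.03 without Gata5-null-labelled replicate 3. The call of the list was lost without double-heterozygous-labelled replicate 2 or 3 (means 0.08 and 0.05, adjusted p = 0.145 and 0.446) and without Gata5-null-labelled replicate 3 or 4 (means 0.10 and 0.03, adjusted p = 0.166 and 0.449), and its mean was 0.17 without double-heterozygous-labelled replicate 1. The endothelial call was also lost with the replicate number as a block (mean 0.06, adjusted p = 0.0838) and without both libraries that stand apart (mean 0.10, adjusted p = 0.200). It was lost too with the covariate of genes at 0 (mean 0.13, adjusted p = 0.432) and with replicates 1 to 3 only (mean 0.08, adjusted p = 0.0713). The 4 Y-linked genes, a check of the sex makeup of the pools, were lower with a mean of -0.67 (adjusted p = 0.0330, and adjusted p = 0.940 with an estimated correlation), from -0.46 [-0.66 to -0.26] for Kdm5d and -0.56 [-1.10 to -0.28] for Ddx3y to -0.70 [-1.15 to -0.45] for Uty and -0.97 [-1.51 to -0.62] for Eif2s3y. That call was lost without any of double-heterozygous-labelled replicates 1, 3 and 4 (adjusted p = 0.1003, 0.0908 and 0.356) and Gata5-null-labelled replicates 1 and 2 (adjusted p = 0.163 and 0.299), and with the covariate of genes at 0 (adjusted p = 0.142). The Y-linked mean was -0.41 without double-heterozygous-labelled replicate 4 and -1.09 without Gata5-null-labelled replicate 4. Against wildtype the Y-linked mean was -0.49 in the Gata5-null-labelled (adjusted p = 0.122) and 0.18 in the double-heterozygous-labelled libraries (adjusted p = 0.672), and neither was called. Among lists not called were the Notch genes (14 of 23 positive, adjusted p = 0.302, with Mfng at 0.87, Maml2 at 0.29 [0.06 to 0.43] and Dtx1 at -0.64 [-0.83 to -0.34]) and the GATA genes (7 of 14 positive, adjusted p = 0.818, with Gata6 at 0.29 and Zfpm2 at 0.17 [0.05 to 0.26]). The collagen list (7 of 21 positive, adjusted p = 0.925) had Col15a1 at -0.19 [-0.29 to -0.05], Col6a2 at -0.18 [-0.22 to -0.09] and Col3a1 at -0.13 [-0.17 to -0.05]. The proteoglycan list (7 of 21 positive, adjusted p = 0.818) had Acan at 0.48, Cd44 at -0.28 [-0.34 to -0.19] and Podn at -0.65, and the elastic fibre list (6 of 18 positive, adjusted p = 0.818) had Mfap2 at 0.63, Loxl1 at -0.28 and Mfap4 at -0.33. Camera called 7 lists, 5 higher and 2 lower, of which 0 were called with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry. The count was 3 without double-heterozygous-labelled replicate 1 or Gata5-null-labelled replicate 4.

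Both comparisons with wildtype use the same 4 wildtype libraries. No gene was called in both by edgeR, since the double-heterozygous-labelled libraries had none. DESeq2 shared 1 gene, Gm29253, higher in both, which had counts in only 1 of the double-heterozygous-labelled libraries. At an unadjusted p under 0.05, 146 genes moved the same way in both, 106 higher and 40 lower, and 0 moved opposite ways. Independent lists of these sizes would share 3.18 and 2.89 genes. Simulated groups without any change that share 4 control libraries gave a mean of 212.7 shared genes, at most 237. The covariance of both sets of log2 fold changes across 13893 genes was 0.0828, against 0.115 (0.104 to 0.126) in 50 such simulations, and genes are not independent replicates. The observed covariance lay below every simulation, so the simulated spread did not match that of these libraries. The simulations therefore cannot decide whether the overlap is larger than the shared libraries give. With the wildtype libraries split so that each comparison had its own 2, the correlation of fold changes across genes was between -0.0378 and 0.0426 in 6 splits, and 10 to 37 genes were shared at an unadjusted p under 0.05.

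Genes near a targeted locus can carry sequence of another mouse strain, so the calls were compared by position. Notch1 and Gata5 are both on chromosome 2. Of the 5 called genes, 0 lay within 20 Mb of either, against 3.14% of the other genes (Fisher's exact p = 1, two-sided). With so few calls and so small a share, 0 was likely in any case, so this test cannot exclude such an effect. Of the genes at an unadjusted p under 0.05 in Gata5-null-labelled against wildtype, 2.98% did (Fisher's exact p = 0.853).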

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

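In 351 groups of 4 libraries, a library stood apart in 17, by its gap to the nearest other library relative to the range of the group. Chance gives about 17.6 of 351, so the number itself is no excess, and no explanation was tested for any of them. The targeted gene Gata5 was at 0.728 CPM in double-heterozygous-labelled replicate 4, against 4.94 to 5.66 CPM in the other 3 libraries of its group. In that library Ndufs4 was at 94.3 CPM against 52.6 to 59.5. Comp was at 92.0 CPM in double-heterozygous-labelled replicate 1 against 52.7 to 56.8, and Prox1 at 69.8 CPM in replicate 3 against 50.6 to 51.4.

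In wildtype, Cilp was at 87.5 CPM in replicate 1 against 66.7 to 69.2 in the others, Klf2 at 41.1 CPM in replicate 2 against 19.3 to 22.3, Gata6 at 82.0 CPM in replicate 3 against 103 to 106, and Myh7 at 331 CPM in replicate 4 against 119 to 129.

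In the Gata5-null-labelled libraries, replicate 1 had Myh7 at 689 CPM against 156 to 240, Ndufb9 at 146 CPM against 206 to 209 and a score of matricellular proteins of 6.75 against 6.55 to 6.56. Replicate 2 had Lfng at 4.01 CPM against 12.8 to 13.5. Replicate 3, the library with the most genes at 0, had Hapln1 at 50.5 CPM against 22.2 to 26.6, Hand2 at 49.4 CPM against 36.7 to 38.2, Klf2 at 67.6 CPM against 26.03 to 31.8 and Col6a2 at 370.3 CPM against 482 to 493. Replicate 4 had Ldb3 at 229 CPM against 193 to 199.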

How the results depend on the processing

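Chosen after the data were seen were the fit without both libraries that stand apart (wildtype replicate 2 and Gata5-null-labelled replicate 3), the covariate of genes at 0, both settings for the libraries numbered 4, the Y-linked covariate for lists and genes, both filters, the 8 libraries and quality weights for named genes, DESeq2 at the authors' thresholds for calls or on all deposited genes, and the unadjusted threshold by position. Elastin and the endothelial score were used only in the tests on scores below, not as covariates of the gene fits. Over the alternatives run, named genes gave 3065 values with the same direction and side of the threshold, 25 that lost a call (5 of them in the fit of the 8 libraries), 3 that gained one and 11 that changed sign. Most named genes were not called in the main fit and had no call to lose, so the 3065 is no measure of stable calls. The 25 losses fell on the 5 called genes, each with 23 alternatives: Cnn1 lost its call in 10, Myh11 in 6, Mylk in 4, Synpo2 in 3 and Itih4 in 2. Called lists gave 345, 53, 0 and 16, without the estimated correlation and fry, which stand below as counts. Where a cause is not named, the cause was not tested.

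For Gata5-null-labelled against wildtype, the 5 called genes became 8 at the authors' thresholds, 45 with DESeq2, 62 with DESeq2 at the authors' thresholds, 2 without both libraries that stand apart (Itih4 and none of the 4 contractile genes), 11 with an indicator of the libraries numbered 4, and 0 with only the 8 libraries or with the Y-linked covariate. Leaving out 1 library gave 2 to 21. The 9 called lists became 0 with an estimated correlation, 1 with fry and 14 with replicates 1 to 3 only. With the replicate number as a block, 7 genes were called. Of 12 pairs of groups and numbers, 1 had a residual correlation over 0.1, and 4 correlated best with their own number. The libraries numbered 4 did so in each comparison (0.0931, 0.213 and 0.0976). They also had the lowest share of counts in Malat1 of their groups (3.23%, 3.53% and 3.70%), a gene chosen after its values were seen. The labels give no batch, and why these libraries resemble each other was not tested.

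For double-heterozygous-labelled against wildtype, DESeq2 called 1 gene at either threshold where edgeR called 0. The 7 lists became 0 with an estimated correlation and 0 with fry, and leaving out 1 library gave 2 to 12. For Gata5-null-labelled against double-heterozygous-labelled, the 0 genes became 3 with DESeq2, 12 with it at the authors' thresholds, 2 without both libraries that stand apart, 1 with the covariate of genes at 0, and 0 to 1 when leaving out 1 library. The 7 lists became 0 with an estimated correlation, 0 with fry and 3 to 7 when leaving out 1 library. Fitted log2 values for Gata5, which is at 0 in 1 group and has no fold beyond its bound, passed the threshold with DESeq2 (-7.45 against wildtype, -8.65 against the double-heterozygous label) and without both libraries that stand apart (-9.35 against the double-heterozygous label). The shared calls became 1 with DESeq2. The authors' 33 calls compare with 8 in edgeR, 62 in DESeq2 on the filtered genes and 66 on all deposited genes at their thresholds. Of the DESeq2 calls, 4.76% lay near Notch1 or Gata5, above the 3.14% of other genes where the edgeR calls were below it (Fisher's exact p = 0.382).

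Signs changed as follows. Without both libraries that stand apart, Gata5-null-labelled against wildtype gave Ndufa2 -0.089, Ndufa4 -0.015, Uqcrc2 -7.9e-05, the ventricular list -0.023 and oxidative phosphorylation -0.063, and double-heterozygous-labelled against wildtype gave Ldb3 -0.040, Ckmt2 -0.023 and the ventricular list -0.13. The fatty acid oxidation mean for Gata5-null-labelled against wildtype kept its sign, but fell to 0.021 without both libraries that stand apart (adjusted p = 0.463) and to 0.031 with the heart muscle covariate (adjusted p = 0.0775). With the heart muscle covariate oxidative phosphorylation was -0.055, and the ventricular list, from which that score is made, -2.3e-04 in double-heterozygous-labelled against wildtype. With the covariate of genes at 0, Klf2 was -0.22 and Maml2 -0.11 in the comparison of both mutant groups. With the Y-linked covariate, by construction, Kdm5d was 0.12, Ddx3y 0.21 and the Y-linked list 0.032 there. Leaving out 1 library gave a range of -0.040 to 0.32 for Ldb3 and -0.022 to 0.44 for Ckmt2 (double-heterozygous-labelled against wildtype). For oxidative phosphorylation it gave -0.067 to 0.26 and for the ventricular list -0.036 to 0.34 (Gata5-null-labelled against wildtype). For the ventricular list it gave -0.13 to 0.26 (double-heterozygous-labelled against wildtype) and -0.066 to 0.27 (both mutant groups). For the atrial list it gave -0.71 to 0.19 (double-heterozygous-labelled against wildtype), and for fatty acid oxidation -0.027 to 0.23 (both mutant groups). Depth limits genes such as Gata5, with 15 to 112 counts where present. In simulations whose spread did not match that of these libraries, 11 to 16 of 100 shifts of 0.75 were called.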

Other observations

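The tests of explanations in this part were chosen after the result was seen, and the counts over splits of the libraries were planned. Among gene groups not described above, none was called in Gata5-null-labelled against wildtype. Of interferon response genes 18 of 25 were positive (adjusted p = 0.202), of class II antigen presentation genes 7 of 8 (adjusted p = 0.131) and of cell cycle genes 17 of 30 (adjusted p = 0.384). Macrophage and monocyte markers had 14 of 23 negative (adjusted p = 0.220), and matrix proteases and inhibitors 15 of 25 (adjusted p = 0.197). Osteogenic genes had 9 of 15 positive (adjusted p = 0.236), and genes of endothelial-to-mesenchymal transition 9 of 20 (adjusted p = 0.220). The signalling lists of BMP and TGF-beta (11 of 25 positive, adjusted p = 0.739) and Wnt (14 of 25, adjusted p = 0.479) went both ways. Markers of valve interstitial cells and fibroblasts had 11 of 20 positive (adjusted p = 0.236), and matricellular genes 11 of 22 (adjusted p = 0.0982).

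Markers of other cell types that a dissection could bring were not called in that comparison: skeletal muscle (adjusted p = 0.202), adipocytes (0.984), lymphocytes (0.218), neutrophils and mast cells (0.229), melanocytes (0.504), Schwann cells (0.878) and mesothelium (0.202). Nor were handling stress (adjusted p = 0.269), hypoxia and glycolysis (0.504), the unfolded protein response (0.748), apoptosis (0.976) or inflammatory cytokines (0.748). The skeletal muscle score, though its list was not called, did not overlap between the groups. It was 0.28 to 1.39 in wildtype and -1.37 to 0.21 in the Gata5-null-labelled libraries. The mean and the median differed in sign for Wnt (-0.11 and 0.03), hypoxia and glycolysis (-0.07 and 0.04), Schwann markers (-0.17 and 0.04) and handling stress (0.04 and -0.03). For the first 2 the test pointed up, as it did for the transition list and the unfolded protein response, whose means were -0.04 and -0.03.

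The 5 genes called in Gata5-null-labelled against wildtype were more than any other split gave. All 35 splits of the 8 libraries were fitted with the double-heterozygous-labelled libraries kept in the model. Of these, 1 split gave as many genes, the real one, and the highest of the others was 1. That is the smallest share that 35 splits can give, and it was reached in 1 of the comparisons tested. It argues against chance for that count in this model but does not exclude it, and a fit of the 8 libraries alone called 0 genes. For the other comparisons the count was 0, 35 of 35 splits gave as many and the highest other was 0. Chance is not excluded for the number of called lists. It was 9 against a highest other of 19 for Gata5-null-labelled against wildtype (13 of 35 splits gave as many). It was 7 against 16 for double-heterozygous-labelled against wildtype (25 of 35), and 7 against 13 for both mutant groups (18 of 35). The calls use a preset correlation of 0.01, while the estimate was up to 0.963 (mitochondrially encoded genes), so a correlation set too low would also give many calls in splits that mix the groups, and neither this nor another structure of the samples was tested. At an unadjusted p under 0.05, 13 of the 35 splits gave at least the 1044 genes of the real split, up to 1689.

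The smooth muscle list's absolute mean of 0.430 was the highest of the 35 splits in Gata5-null-labelled against wildtype (highest other 0.367), though 15 of the 35 called the list. It was not the highest in double-heterozygous-labelled against wildtype (0.178 against 0.203, with 4 of 35 as large) or for both mutant groups (0.252 against 0.271, with 2 of 35 as large), so chance is not excluded there either. For Gata5-null-labelled against wildtype the score was lower by -0.49 (SE 0.11) on the members with a mean log2 CPM of at least 1. Without both libraries that stand apart the difference was -0.347 (SE 0.0924), and with the Y-linked score as a covariate -0.397 (SE 0.111), which argues against either as the whole cause. A smaller share of elastin-rich aortic wall in the pools cannot be told apart from lower expression in the cells present. The score minus the log2 CPM of Eln differed by 0.00226 (SE 0.173), but this only restates a lower Eln (-0.49, SE 0.18), 1 gene that smooth muscle cells themselves express, while the elastic fibre list had 9 positive and 9 negative members. An effect of the genotype on the cells present stays open and was not tested.

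The Y-linked covariate ended the 5 calls while their fold changes moved little. Itih4 went from -1.17 (SE 0.17) to -1.08 (SE 0.19), Synpo2 from -0.83 (SE 0.13) to -0.74 (SE 0.13) and Mylk from -0.75 (SE 0.12) to -0.72 (SE 0.13). Myh11 went from -0.75 (SE 0.12) to -0.71 (SE 0.14) and Cnn1 from -0.81 (SE 0.15) to -0.75 (SE 0.16). Smaller folds, wider errors and 1 term more in the model left the adjusted p between 0.101 and 0.475. The sex makeup of the pools is not in the labels.

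Notch1 was higher by 0.54 (SE 0.17) on the log2 scale in Gata5-null-labelled than in wildtype libraries, a difference that was not called over all genes. With the Y-linked score as a covariate it was 0.587 (SE 0.198), which argues against the sex makeup of the pools as the whole cause. After subtraction of the endothelial score it was 0.444 (SE 0.155). This only restates that the endothelial score rose by less than Notch1 did (0.097, SE 0.115). It argues against a larger share of endothelial cells as a set as the whole cause, if Notch1 follows that share as the score does. A larger share of 1 endothelial cell type was not tested. Reads from the targeted allele and an effect of the genotype stay open, as untested.

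The score of oxidative phosphorylation was higher by 0.133 (SE 0.266) in Gata5-null-labelled than in wildtype libraries, within the spread between replicates. With the cardiomyocyte score as a covariate it was -0.0644 (SE 0.0648), and without both libraries that stand apart -0.0768 (SE 0.247). A different share of heart muscle in the pools, or those libraries, may account for the list's call, and the covariate could also remove a change within heart muscle cells. An effect of the genotype was not tested apart from these.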
